A study of Mus musculus with 18 samples.

How the data were processed

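Messenger RNA was measured in proximal colon of C57BL/6 mice, with 18 libraries in 6 groups of 3. Per the labels, tissue pieces of 10 to 30 mg were kept in RNAlater, RNA was extracted with a column kit after bead beating, and mRNA libraries were sequenced on a HiSeq to 43 ± 3 M paired reads of 50 nt. The submitters' processing notes name HISAT and StringTie, without versions, and the genome build mm10.

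The deposited tables list the same 259888 exons for each library. Per the file headers they hold, for each exon, a count of reads overlapping it, a count of uniquely mapped reads, an expected count in which reads that map to several places are weighted, and a coverage signal per base. The uniquely mapped read count was used here. Exons were joined to GENCODE vM21 genes by exact coordinates and strand, and 197233 exons, or 75.9%, matched exactly 1 gene; 1847 matched several genes, 60808 matched none exactly, and 2729 had no strand. For each of 22502 genes, counts were summed over exons that do not overlap each other, 192061 in all. A spliced read is counted in each exon it touches, so the sums of 41.86 to 60.84 M per library are not numbers of reads, and reads estimated from coverage came to 37.86 to 55.05 M. The exons that matched exactly 1 gene, including those that overlap each other, held 48.4 to 51.9% of exon reads outside the mitochondrial chromosome. The files do not give strandedness, so reads were treated as unstranded. In 1151 tested genes over 50% of the bases used lay in exons that overlap an exon of another gene. An exon was counted in full if any part of it overlapped.

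Tests used edgeR 4.0.16 with quasi-likelihood fits, TMM scaling and filterByExpr, which kept 15714 genes, in 1 model with a mean for each of 6 groups. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.239. The 10 comparisons were DSS with water as the mean of the diets and on each diet, TD.09052 with TD.09054 on water and on DSS, TD.130633 with the mean of the other diets on water and on DSS, and the difference between DSS responses for the same pairs of diets. Log2 fold changes came from the edgeR fits with the default prior count. The SE of a gene's change was derived from it, as its absolute value divided by the square root of the quasi-likelihood F statistic. Log2 CPM values for list tests, list means and principal components were computed with a prior count of 2. Of 41 gene lists, written from general knowledge, 40 had at least 5 tested members and were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry, which tests the direction of a list on its own and not against other genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and DESeq2 1.42.0 were also used.

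Genes were named by a rule. Among called genes with a mean of at least 5 CPM over the 18 libraries and, except for differences of responses, no overlap of the compared groups, the 10 largest changes per direction were taken, and up to 4 called genes of each list with the largest changes were added. Symbols of the form Gm plus digits, Rik clones, immunoglobulin and T cell receptor segments and some unnamed features were left out of those 10. The comparisons, the rule and the lists were written before the data were examined. Other settings, chosen in advance, were all overlapping reads per exon, reads corrected for multiple mapping, reads from base coverage, all exons including overlapping ones, median-of-ratios size factors, no filter beyond 1 count, the letter in each title as a replicate block, the DESeq2 Wald test, a fit of the groups of a comparison alone, a single diet as the comparator of TD.130633, and leaving out each library in turn. Exons assigned to genes by overlap (26299 genes) and leaving out the 3 libraries that lay farthest from their group were chosen after seeing the data.

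The pipeline was tested on simulated data, with 200 genes changed by 1.5, 2 or 4 times in each of 6 comparisons. Group labels were exchanged in 10 splits for comparisons of 3 with 3 libraries and 100 for larger ones. It was checked that no pair of libraries is identical. Genes without an exact exon match and exons that match several genes were left out, and transcript isoforms and splicing were not analysed here. What the diets contain besides psyllium was not used here.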

Results

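RNA was sequenced from the proximal colon of 18 C57BL/6 mice, with 3 mice in each of 6 groups. Each mouse ate 1 of 3 diets, named TD.130633, TD.09054 and TD.09052, and then drank either plain water or 3% dextran sulfate sodium (DSS), a polysaccharide that injures the lining of the colon, for 3 days. TD.130633 alone contained psyllium, a gel-forming plant fibre, and the remaining diets served as controls of each other; what else the diets held was not used here. The libraries held 41.86 to 60.84 M unique exon reads in genes, with a spliced read counted in each exon it touched. Unless stated otherwise, a level is the mean ± SD in normalised counts (CPM) of 3 mice, and a change is a log2 fold change ± SE from 1 edgeR model of all 18 libraries, in which 15714 genes were tested. Chromosome positions refer to mm10. The gene lists, the comparisons and the rule for naming genes were fixed before the data were examined.

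Principal components set most DSS libraries apart from most water libraries. The first component held 30.3% of the variance and the second 19.3%. Water libraries lay between -52.7 and -15.1 on the first component, except TD.09052 Water replicate 2 at 23.2, and DSS libraries lay between 1.4 and 88.9. The 3 TD.130633 DSS libraries had the highest values on the second component, at 91.4, 43.2 and 32.5. TD.130633 DSS replicate 1, TD.09054 DSS replicate 2 and TD.09052 Water replicate 2 lay farthest from their groups, and values without these 3 libraries, an alternative chosen after seeing the data, are given where they differ by over 1.5 times.

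**Figure D1:**
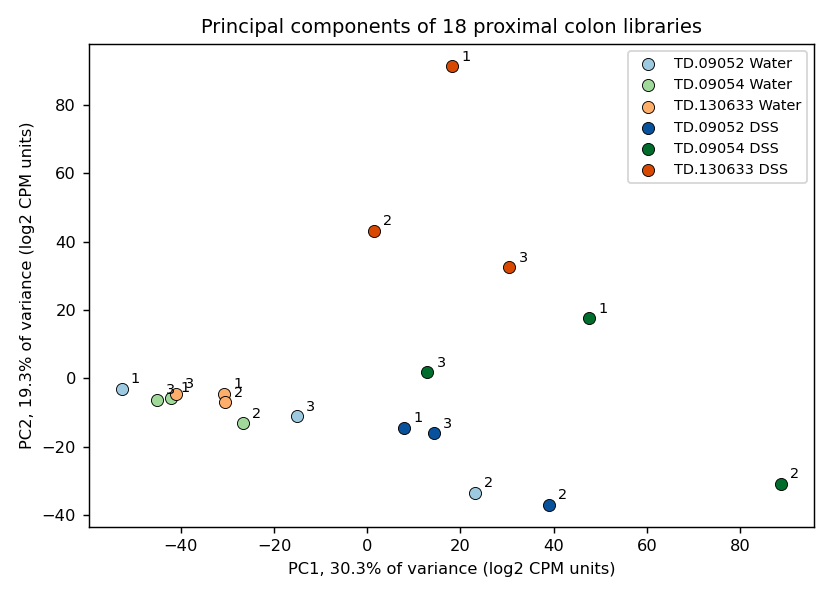
First principal component (horizontal axis, 30.3% of the variance) against the second (vertical axis, 19.3%) of log2 CPM, with 1 point per library, coloured by group and numbered by replicate. Water libraries lie to the left, apart from TD.09052 Water replicate 2 at 23.2, and TD.130633 DSS replicate 1 lies highest at 91.4.

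**Figure D2:**
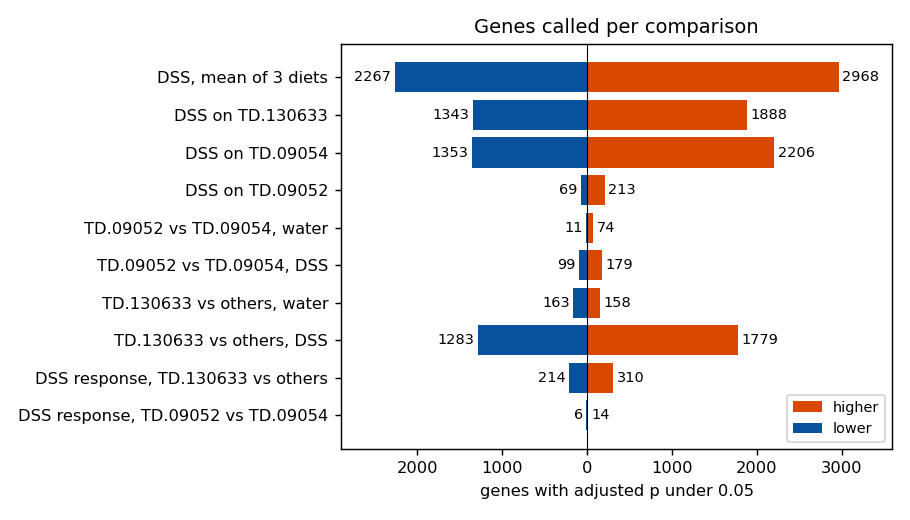
Number of genes called higher or lower (horizontal bars, edgeR, adjusted p under 0.05) in each of the 10 comparisons, of 15714 genes tested. DSS called 3231 genes on TD.130633, 3559 on TD.09054 and 282 on TD.09052.

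DSS was compared with water as the equal-weight mean over the 3 diets, the inflammation part of the design. Genes of the muscle and connective tissue of the colon wall rose. Svep1, which encodes an extracellular matrix protein (chromosome 4, 58042442 to 58206859), went from 19.7 ± 7.43 to 67.5 ± 6.3 CPM on TD.09052, from 11.7 ± 2.01 to 76.6 ± 6.67 on TD.09054 and from 11.7 ± 1.48 to 39.6 ± 13.6 on TD.130633 (2.08 ± 0.15, adjusted p = 4.68e-07). All 14 tested smooth muscle genes rose, also 14 adjusted over the list alone, with a median of 0.90; examples were Lmod1, an actin nucleator of muscle, at 1.13 ± 0.09 and Acta2, smooth muscle actin, at 1.07 ± 0.10. The camera test of the list gave an adjusted p = 4.32e-13, and an adjusted p = 0.136 with an estimated correlation. Of 20 fibroblast and matrix genes 19 rose (19 adjusted over the list alone; median 1.06), among them the matrix glycoproteins Tnc at 1.76 ± 0.17 and Fn1 at 1.66 ± 0.19. Camera gave the list an adjusted p = 2.11e-08, and an adjusted p = 0.436 with an estimated correlation. Of 16 enteric neuron and glia genes 14 rose (14 adjusted over the list alone), among them the glial regulator Sox10 at 1.10 ± 0.11 and the neuropeptide gene Vip at 1.24 ± 0.16. The list as a whole had a camera adjusted p = 2.51e-07, and an adjusted p = 0.294 with an estimated correlation. Of 14 endothelial genes 13 rose (13 adjusted over the list alone), with Plvap, a protein of capillary diaphragms, at 0.92 ± 0.10. As a set these genes had a camera adjusted p = 3.49e-08, and an adjusted p = 0.344 with an estimated correlation. Smooth muscle, neuron and glia and endothelial genes moved by like amounts, with list means of 0.91 ± 0.08, 0.81 ± 0.11 and 0.72 ± 0.10 (SE).

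Among genes of ion and water transport, more fell than rose with DSS. Scnn1g, the gamma subunit of the epithelial sodium channel (chromosome 7, 121734479 to 121768475), fell by 2.58 ± 0.22 on the log2 scale (adjusted p = 1.22e-06), for example from 64.2 ± 5.81 to 3.53 ± 1.21 CPM on TD.130633. Scnn1b, the beta subunit, changed by -1.39 ± 0.14 and Sgk1, a kinase that keeps the channel at the cell surface, by -1.89 ± 0.22. Of 23 ion and water transport genes 15 fell and 3 rose (16 and 3 adjusted over the list alone; camera adjusted p = 0.00024, and adjusted p = 0.136 with an estimated correlation). Of 15 crypt base and Wnt target genes 7 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.28 and a mean of -0.69 (camera adjusted p = 0.000116, and adjusted p = 0.103 with an estimated correlation). Of 25 cell cycle genes 13 fell (15 adjusted over the list alone), among them the kinesin Kif11 at -0.82 ± 0.20 and the topoisomerase Top2a at -0.76 ± 0.23. Tested together with camera, they had an adjusted p = 1.68e-05, and an adjusted p = 0.672 with an estimated correlation. On TD.130633 none of the 25 was called in edgeR and their median was 0.26, with Kif11 at 27.9 ± 4.67 CPM on water and 28.4 ± 11.5 with DSS. The cell cycle count was 24 without TD.130633 DSS replicate 1 and 25 without the 3 libraries that lay apart. Of 24 oxidative phosphorylation genes 17 fell (18 adjusted over the list alone) by small amounts, with a median of -0.19 and Ndufa1, a complex I subunit, at -0.50 ± 0.05. Their camera test gave an adjusted p = 7.34e-07, and an adjusted p = 0.647 with an estimated correlation. Saa1, an acute-phase protein made by colon epithelium, fell from 2660 ± 221 to 1400 ± 343 CPM on TD.09054 and from 2100 ± 334 to 494 ± 171 on TD.130633 (mean of the diets -1.29 ± 0.13, adjusted p = 6.64e-06).

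Macrophage genes and some antimicrobial genes rose. Of 14 macrophage and monocyte genes 12 rose (14 adjusted over the list alone), among them the lysosomal marker Cd68 at 1.61 ± 0.26 and the high-affinity antibody receptor Fcgr1 at 2.04 ± 0.34. Camera gave the list an adjusted p = 0.000119, and an adjusted p = 0.647 with an estimated correlation. By diet the list medians were 0.40 on TD.09052, where 0 were called in edgeR, 1.57 on TD.09054 and 1.34 on TD.130633. Reg3b, a secreted antibacterial lectin, had 0.0852 ± 0.0739, 0.124 ± 0.0835 and 0.0613 ± 0.0781 CPM on water and 0.92 ± 1.28, 44.2 ± 54.9 and 25.5 ± 20.5 CPM with DSS on TD.09052, TD.09054 and TD.130633 (adjusted p = 0.000218). Of 20 antimicrobial genes 8 rose and 4 fell (camera adjusted p = 0.526). Their medians were -0.25 on TD.09052, where 0 were called in edgeR, 1.37 on TD.09054 and 0.98 on TD.130633. The mucin gene Muc2, the main component of colonic mucus, rose by 0.68 ± 0.09 (adjusted p = 4.77e-05). In all, 5235 of 15714 genes were called, 2968 higher and 2267 lower. In 1035 of them the DSS and water libraries did not overlap within any of the 3 diets, and over all tested genes the number was also 1035. Of 154 named genes called, 123 kept the call whichever single library was left out, including each gene given a value for this comparison.

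**Figure D3:**
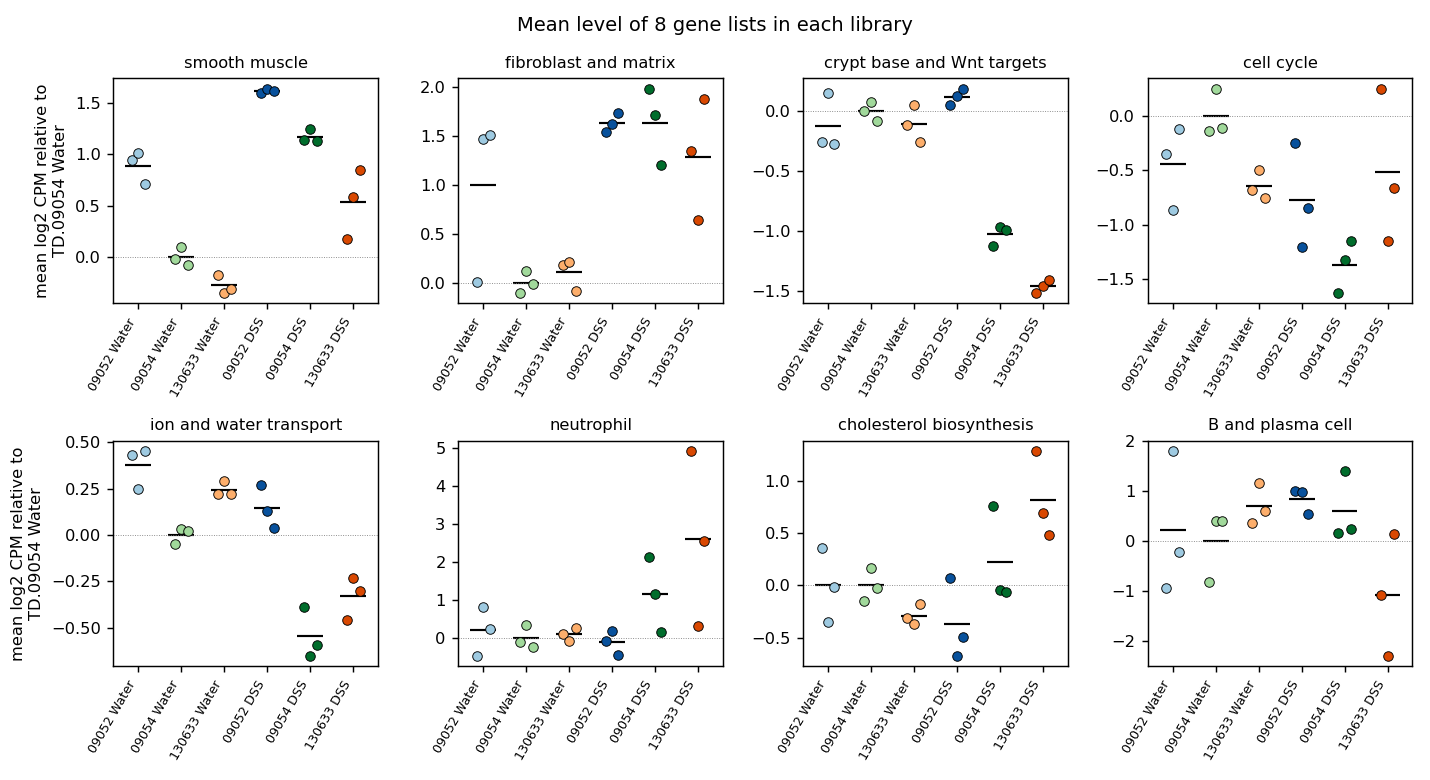
Mean log2 CPM of 8 gene lists relative to TD.09054 Water (vertical axes) in the 6 groups (horizontal axes); points are libraries and lines are group means. Smooth muscle genes lie higher with DSS on each diet, and crypt base genes lie lower with DSS on TD.130633 and TD.09054.

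On TD.130633, the psyllium diet, DSS was compared with water in 3 mice each. Slpi, a secreted protease inhibitor of inflamed mucosa (chromosome 2, 164354070 to 164389095, 27.9% of its bases in exons that overlap another gene), rose from 16 ± 4.54 to 448 ± 251 CPM (4.81 ± 0.49, adjusted p = 3.27e-05). Ephb3, a receptor of crypt base cells and a Wnt target (chromosome 16, 21204755 to 21223305), fell from 72 ± 4.43 to 13.5 ± 2.27 CPM (-2.41 ± 0.17, adjusted p = 1.24e-06). Axin2, another Wnt target (chromosome 11, 108920349 to 108950783), fell from 46.6 ± 11.9 to 4.38 ± 2.17 CPM (-3.40 ± 0.33), and the stem cell marker Lgr5 (chromosome 10, 115450311 to 115587780) fell from 5.47 ± 0.884 to 0.1 ± 0.0541 CPM (adjusted p = 1.24e-06). Of 15 crypt base and Wnt target genes 7 fell (8 fell and 2 rose adjusted over the list alone; camera adjusted p = 4.77e-06, and adjusted p = 0.0277 with an estimated correlation). Cldn2, a pore-forming tight junction protein of crypts (chromosome X, 139800828 to 139811386), fell from 267 ± 13.3 to 30.1 ± 1.37 CPM (-3.15 ± 0.27, adjusted p = 1.31e-05).

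Goblet cell and cholesterol synthesis genes rose on this diet. Of 14 goblet cell genes 7 rose (7 adjusted over the list alone), among them Muc2 from 1450 ± 66.7 to 3260 ± 247 CPM and Agr2, needed for mucin folding, from 673 ± 6.53 to 1510 ± 462 CPM; the count was 4 without TD.130633 Water replicate 2. The list as a whole had a camera adjusted p = 0.00706, and an adjusted p = 0.502 with an estimated correlation. Of 25 cholesterol synthesis genes 19 rose (20 adjusted over the list alone), among them Cyp51 at 2.19 ± 0.42, Idi1 at 2.12 ± 0.46 and Sqle at 1.96 ± 0.42. As a set these genes had a camera adjusted p = 5.38e-08, and an adjusted p = 0.502 with an estimated correlation. Aqp4, a water channel, rose from 13.4 ± 2.23 to 66.1 ± 20.4 CPM (2.31 ± 0.35, adjusted p = 0.000562). Hkdc1, a hexokinase domain protein, fell from 74.6 ± 6.5 to 4.52 ± 1.55 CPM, and S100g, a calcium-binding protein of absorptive cells, from 212 ± 60.9 to 15.4 ± 8.24 CPM. Of 11 neutrophil genes 8 rose (8 adjusted over the list alone) with 2 called without TD.130633 DSS replicate 1 and 4 without the 3 libraries that lay apart. Tested together with camera, they had an adjusted p = 0.0068, and an adjusted p = 0.502 with an estimated correlation. Of 13 B and plasma cell genes 6 fell (6 adjusted over the list alone) and 2 did so without TD.130633 Water replicate 2; Cd79a, part of the B cell receptor, went from 20.1 ± 6.55 to 2.95 ± 2.3 CPM. Their camera test gave an adjusted p = 0.00127, and an adjusted p = 0.502 with an estimated correlation.

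Arg1, an arginase of activated macrophages and myeloid cells, rose from 0.432 ± 0.0999 to 165 ± 253 CPM and Clca4b, a calcium-activated chloride channel regulator, from 1.85 ± 0.672 to 176 ± 229 CPM, with SDs larger than the means. All 14 smooth muscle genes rose (14 adjusted over the list alone; camera adjusted p = 7.78e-09, and adjusted p = 0.367 with an estimated correlation). In all, 3231 genes were called, 1888 higher and 1343 lower. Over all 15714 tested genes, all 3 DSS libraries lay on 1 side of all 3 water libraries in 6006, which chance gives for 10% of genes. Each gene given a value for this comparison kept its call whichever single library was left out. The count was 1918, 1952 and 1868 without TD.130633 Water replicates 1, 2 and 3, and 1581 with these 2 groups fitted alone.

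On TD.09054 the crypt base genes fell, and cell cycle genes fell as well. Ephb3 went from 74.3 ± 5.09 to 21.1 ± 5.48 CPM (-1.81 ± 0.16, adjusted p = 3.32e-05), Axin2 from 48.1 ± 4.51 to 8.78 ± 3.1 CPM (-2.45 ± 0.31) and Lgr5 from 5.75 ± 0.665 to 0.385 ± 0.138 CPM (adjusted p = 3.07e-05). Of 15 crypt base and Wnt target genes 9 fell (11 fell and 1 rose adjusted over the list alone; camera adjusted p = 4.74e-06, and adjusted p = 0.034 with an estimated correlation). Of 25 cell cycle genes 17 fell (18 adjusted over the list alone; median -1.62), among them the spindle checkpoint kinase Bub1 at -2.23 ± 0.42, the mitotic cyclin Ccnb1 at -2.04 ± 0.33 and Kif11 at -1.99 ± 0.36. Camera gave the list an adjusted p = 1.53e-11, and an adjusted p = 0.586 with an estimated correlation. Nox1, the superoxide-producing oxidase of colon epithelium (chromosome X, 134086421 to 134221956), fell from 67.7 ± 14.2 to 10.8 ± 5.47 CPM, although 33.2% of its bases lie in exons that overlap another gene. Cldn2 fell from 292 ± 13.9 to 65.4 ± 38.4 CPM (-2.16 ± 0.26, adjusted p = 0.000111).

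Interferon-induced genes and genes of the colon wall rose on TD.09054. Of 24 interferon-stimulated genes 10 rose (11 adjusted over the list alone) and 6 did so without TD.09054 Water replicate 2; the guanylate-binding protein genes Gbp5 and Gbp3 went from 5.84 ± 0.423 to 28.5 ± 8.92 and from 15.5 ± 2.52 to 60.5 ± 14.3 CPM. The list as a whole had a camera adjusted p = 6.6e-05, and an adjusted p = 0.702 with an estimated correlation. Of 8 major histocompatibility complex class II genes, which present antigen, 5 rose (6 adjusted over the list alone) and 0 did so in edgeR without TD.09054 Water replicate 1. As a set these genes had a camera adjusted p = 0.00634, and an adjusted p = 0.702 with an estimated correlation. Of 14 macrophage and monocyte genes 9 rose (12 adjusted over the list alone), 2 without TD.09054 Water replicate 1 and 3 without the 3 libraries that lay apart; Cd68 went from 3.88 ± 0.814 to 19.7 ± 6.71 CPM. Tested together with camera, they had an adjusted p = 0.000377, and an adjusted p = 0.702 with an estimated correlation. All 14 smooth muscle genes rose (14 adjusted over the list alone; camera adjusted p = 6.16e-13, and adjusted p = 0.156 with an estimated correlation), as did 13 of 14 endothelial genes (13 adjusted over the list alone; camera adjusted p = 1.06e-08, and adjusted p = 0.333 with an estimated correlation). Of 20 fibroblast and matrix genes 16 rose (17 adjusted over the list alone; camera adjusted p = 1.06e-08, and adjusted p = 0.437 with an estimated correlation), with Tnc at 2.03 ± 0.30. In all, 3559 genes were called, 2206 higher and 1353 lower. Over all 15714 tested genes, the DSS and water libraries did not overlap in 6914, against 10% by chance. Each gene given a value kept its call whichever single library was left out. The count was 2015, 2271 and 2190 without TD.09054 Water replicates 1, 2 and 3, and 1943 without TD.09054 DSS replicate 2.

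On TD.09052 fewer genes passed the test, and genes of the colon wall were among those that rose. Svep1 rose by 1.78 ± 0.25 (adjusted p = 0.00986) and Fbln1, an extracellular matrix protein, from 41.8 ± 16.5 to 115 ± 9.78 CPM (1.46 ± 0.22, adjusted p = 0.00986). Of 14 smooth muscle genes 10 rose (14 adjusted over the list alone; median 0.75), among them Acta2 from 1370 ± 151 to 2600 ± 61.8 CPM and Myh11, smooth muscle myosin, from 1970 ± 417 to 3660 ± 317 CPM. Their camera test gave an adjusted p = 3.14e-14, and an adjusted p = 0.341 with an estimated correlation. Igha, the immunoglobulin A heavy chain, rose from 229 ± 130 to 931 ± 77.2 CPM (2.02 ± 0.49, adjusted p = 0.0495). Car1, a carbonic anhydrase of colonocytes (chromosome 3, 14766216 to 14808368), fell from 616 ± 347 to 186 ± 49.4 CPM (-1.73 ± 0.35, adjusted p = 0.0233) and Fxyd4, a regulator of the sodium pump, from 417 ± 199 to 197 ± 19.8 CPM. Of 24 oxidative phosphorylation genes 6 fell (19 adjusted over the list alone; median -0.29), with Cox7b, a cytochrome c oxidase subunit, at -0.56 ± 0.10. Camera gave the list an adjusted p = 9.47e-15, and an adjusted p = 0.699 with an estimated correlation. A set of 20 pan-epithelial genes, none of them called in edgeR, had a median of -0.26. Lgr5 had 6.09 ± 2.13 CPM on water and 5.51 ± 0.395 with DSS, Axin2 32.3 ± 3.73 and 34.4 ± 5.06, and Ephb3 60.7 ± 3.4 and 64.9 ± 7.73, and none of the 15 crypt base and Wnt target genes or the 25 cell cycle genes was called in edgeR.

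In all, 282 genes were called on TD.09052, 213 higher and 69 lower, of 2718 with an unadjusted p under 0.05. Among all 15714 tested genes the DSS and water libraries did not overlap in 3741, against 10% by chance. None of the 35 named genes that were called, Svep1, Acta2 and Car1 included, kept the call in all 6 leave-outs. The count was 4, 925 and 0 without TD.09052 Water replicates 1, 2 and 3, and 82, 88 and 0 without TD.09052 DSS replicates 1, 2 and 3; none of the 10 smooth muscle and 6 oxidative phosphorylation genes was called in edgeR without TD.09052 Water replicate 1. It was 964 with DESeq2, 11 with these 2 groups fitted alone and 2570 without the 3 libraries that lay apart, when 14 smooth muscle genes rose and 19 oxidative phosphorylation genes fell.

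Genes called with DSS overlapped between diets, which share no library. TD.130633 and TD.09054 shared 915 higher genes, against 265 by chance, and 392 lower genes, against 115.6. TD.09052 shared 173 higher genes with TD.130633, against 25.6, and 203 with TD.09054, against 29.9, and it shared 17 and 21 lower genes, against 5.9 each. Of the genes called on TD.130633, 84.3% had the same sign on TD.09054 and 66.9% on TD.09052, and of those called on TD.09054, 90.4% had it on TD.09052. Over all genes these shares were 64.6%, 56.1% and 70.6%.

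TD.09052 was compared with TD.09054 on water, as the design names these diets controls of each other. Cyp2c55, a cytochrome P450 enzyme of fatty acid and drug oxidation (chromosome 19, 39007019 to 39042693, 14.8% of its bases in exons that overlap another gene), was at 1220 ± 511 CPM on TD.09052 and 89.2 ± 16 CPM on TD.09054 (3.78 ± 0.42, adjusted p = 0.000367). Actg2, enteric smooth muscle actin (chromosome 6, 83512905 to 83536265), was at 1520 ± 39.8 and 406 ± 72.3 CPM (1.90 ± 0.15, adjusted p = 2.71e-05). Of 14 smooth muscle genes 7 were higher on TD.09052 (13 adjusted over the list alone, median 0.85), with Cnn1, calponin, at 1.24 ± 0.12 and Des, muscle desmin (66.5% of its bases lie in exons that overlap another gene), at 1.33 ± 0.12. The count was 4 without TD.09054 Water replicate 1. The list as a whole had a camera adjusted p = 1.69e-27, and an adjusted p = 0.0336 with an estimated correlation. The list means of neuron and glia genes, 0.13 ± 0.19, and of endothelial genes, 0.28 ± 0.24 (SE), lay below that of smooth muscle genes, 0.89 ± 0.11. Medians of 1.26 for 20 fibroblast and matrix genes and 1.96 for 10 adipocyte genes lay above that of smooth muscle genes, although none of either list was called in edgeR (13 and 0 adjusted over the list alone). Their camera adjusted p were 1.03e-10 and 0.0485, with an adjusted p = 0.813 and an adjusted p = 0.891 with an estimated correlation. Abcg8, which with Abcg5 exports sterols from the cell, was higher at 1.81 ± 0.27 (adjusted p = 0.00465). Gsdmc2, a gasdermin of colon epithelium, was lower, at 326 ± 29 against 507 ± 34.5 CPM (-0.64 ± 0.09, adjusted p = 0.00178).

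In all, 85 genes differed between these diets on water, 74 higher and 11 lower on TD.09052. Of all 15714 tested genes, 2274 had no overlap between these groups, against 10% by chance. Of 22 named genes called, Cyp2c55, Actg2, Abcg8, Gsdmc2, Des and Cnn1 kept the call in each leave-out. The count was 21, 33 and 20 without TD.09054 Water replicates 1, 2 and 3, and 212, 41 and 48 without TD.09052 Water replicates 1, 2 and 3. It was 257 with DESeq2, 45 with these 2 groups fitted alone and 138 without the 3 libraries that lay apart.

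With DSS, TD.09052 had higher levels of crypt base genes than TD.09054. Lgr5 was at 5.51 ± 0.395 CPM on TD.09052 and 0.385 ± 0.138 on TD.09054 (adjusted p = 3.37e-05), and Ephb3 at 64.9 ± 7.73 and 21.1 ± 5.48 CPM (1.62 ± 0.16, adjusted p = 0.000106). Higher too were 7 of 15 crypt base and Wnt target genes (10 adjusted over the list alone), among them Axin2 at 1.97 ± 0.31. As a set these genes had a camera adjusted p = 1.23e-12, and an adjusted p = 0.000807 with an estimated correlation. Cldn2 was at 237 ± 12.5 and 65.4 ± 38.4 CPM (1.86 ± 0.26, adjusted p = 0.00208). Cyp2c55 was at 1080 ± 30.5 and 34.9 ± 3.95 CPM (4.95 ± 0.45, adjusted p = 3.96e-05) and Abcb1a, a drug efflux pump, at 1690 ± 154 and 510 ± 81.1 CPM (1.73 ± 0.22). Of 23 ion and water transport genes 4 were higher (8 adjusted over the list alone), 2 without TD.09052 DSS replicate 1 and 8 without the 3 libraries that lay apart. Tested together with camera, they had an adjusted p = 1.07e-06, and an adjusted p = 0.0346 with an estimated correlation. They included Slc9a3, the apical sodium and proton exchanger (chromosome 13, 74121457 to 74169442), at 11.2 ± 5.43 and 0.294 ± 0.197 CPM, and Kcnq1, a potassium channel, at 1.22 ± 0.17. Of 24 interferon-stimulated genes 5 were lower (10 adjusted over the list alone), and 0 were called in edgeR without TD.09052 DSS replicate 1. Their camera test gave an adjusted p = 1.28e-06, and an adjusted p = 0.551 with an estimated correlation.

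In all, 278 genes differed between TD.09052 and TD.09054 with DSS, 179 higher and 99 lower on TD.09052. Of all 15714 tested genes, 3123 had no overlap between these groups, against 10% by chance. Each gene given a value kept its call whichever single library was left out, as did 26 of 53 named genes called. The count was 136 without TD.09054 DSS replicate 1, and 103, 180 and 117 without TD.09052 DSS replicates 1, 2 and 3. It was 706 with DESeq2, 155 with these 2 groups fitted alone and 587 without the 3 libraries that lay apart. Water and DSS comparisons of these diets shared 22 higher genes, against 0.8 by chance, and 6 lower genes, against 0.1, with no library in common. Over all genes the changes on water and with DSS had the same sign in 47.1% and a Spearman correlation of -0.07.

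TD.130633 was compared with the mean of the other diets on water, the comparison the design gives for psyllium. Hkdc1 (chromosome 10, 62383137 to 62422491) was at 74.6 ± 6.5 CPM on TD.130633, 12.4 ± 3.62 on TD.09054 and 18.6 ± 6.55 on TD.09052 (2.29 ± 0.31, adjusted p = 0.0024). Enpep, an aminopeptidase of the brush border, was at 31 ± 6.08, 8.15 ± 1.35 and 11.6 ± 3.72 CPM (1.67 ± 0.23, adjusted p = 0.0024), and Slc11a2, the apical iron transporter, at 150 ± 40.6, 80.1 ± 11.8 and 65.2 ± 3.09 CPM (1.06 ± 0.15, adjusted p = 0.00325). Me3, a mitochondrial malic enzyme, was higher at 2.05 ± 0.30. Of 28 amino acid and urea cycle genes 2 were higher (4 adjusted over the list alone), 1 of them Slc6a19, a neutral amino acid transporter, at 2.04 ± 0.32; the count was 1 without TD.130633 Water replicate 1 and 4 without the 3 libraries that lay apart. Camera gave the list an adjusted p = 0.0348, and an adjusted p = 0.274 with an estimated correlation. Of 17 circadian clock genes 2 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.125), and 0 were called in edgeR without TD.130633 Water replicate 1 and 7 without the 3 libraries that lay apart. Per1, a clock repressor, was at 83.5 ± 19, 33.2 ± 2.81 and 47.7 ± 12.9 CPM (1.07 ± 0.21) and Ciart, another, at 8.03 ± 3.63, 1.51 ± 0.784 and 1.38 ± 0.311 CPM. Arntl, the clock activator, was at 63.4 ± 6.99, 133 ± 25.4 and 134 ± 22.5 CPM (-1.08 ± 0.22), and none of these 3 passed against both other diets alone. The clock list was written as a sign of the time of day. A difference in the hour of collection between the groups was not tested as a cause. Hsd3b3, a steroid dehydrogenase, was lower at -1.41 ± 0.21 and the histone gene Hist1h2bc at -1.19 ± 0.16. Of 14 smooth muscle genes 8 were lower (14 adjusted over the list alone; median -0.64), 3 without TD.130633 Water replicate 2 and 14 without the 3 libraries that lay apart. The list as a whole had a camera adjusted p = 2.15e-17, and an adjusted p = 0.172 with an estimated correlation. Among these, Actg2 (-1.30 ± 0.14), Cnn1 (-1.06 ± 0.11) and Des (-1.01 ± 0.11) differed from TD.09052, at -2.25, -1.68 and -1.68, and did not pass the test against TD.09054 alone, at -0.35, -0.44 and -0.35.

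In all, 321 genes differed between TD.130633 and the other diets on water, 158 higher and 163 lower, and in 299 the 3 TD.130633 libraries lay beyond all 6 others. Of 34 named genes called, 10 kept the call in all 9 leave-outs, and these are the genes given values here except Per1, Ciart and Arntl, which lost it at least once. The count was 47, 43 and 68 without TD.130633 Water replicates 1, 2 and 3, 132, 127 and 198 without TD.09054 Water replicates 1, 2 and 3, and 184 without TD.09052 Water replicate 3. It was 870 with DESeq2, 867 with these 3 groups fitted alone, 1501 without the 3 libraries that lay apart and 74 with TD.09054 as the only comparator, against which Hkdc1, Enpep, Slc11a2, Hsd3b3, Hist1h2bc and Slc6a19 still passed and Me3 did not, at 1.60.

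**Figure D4:**
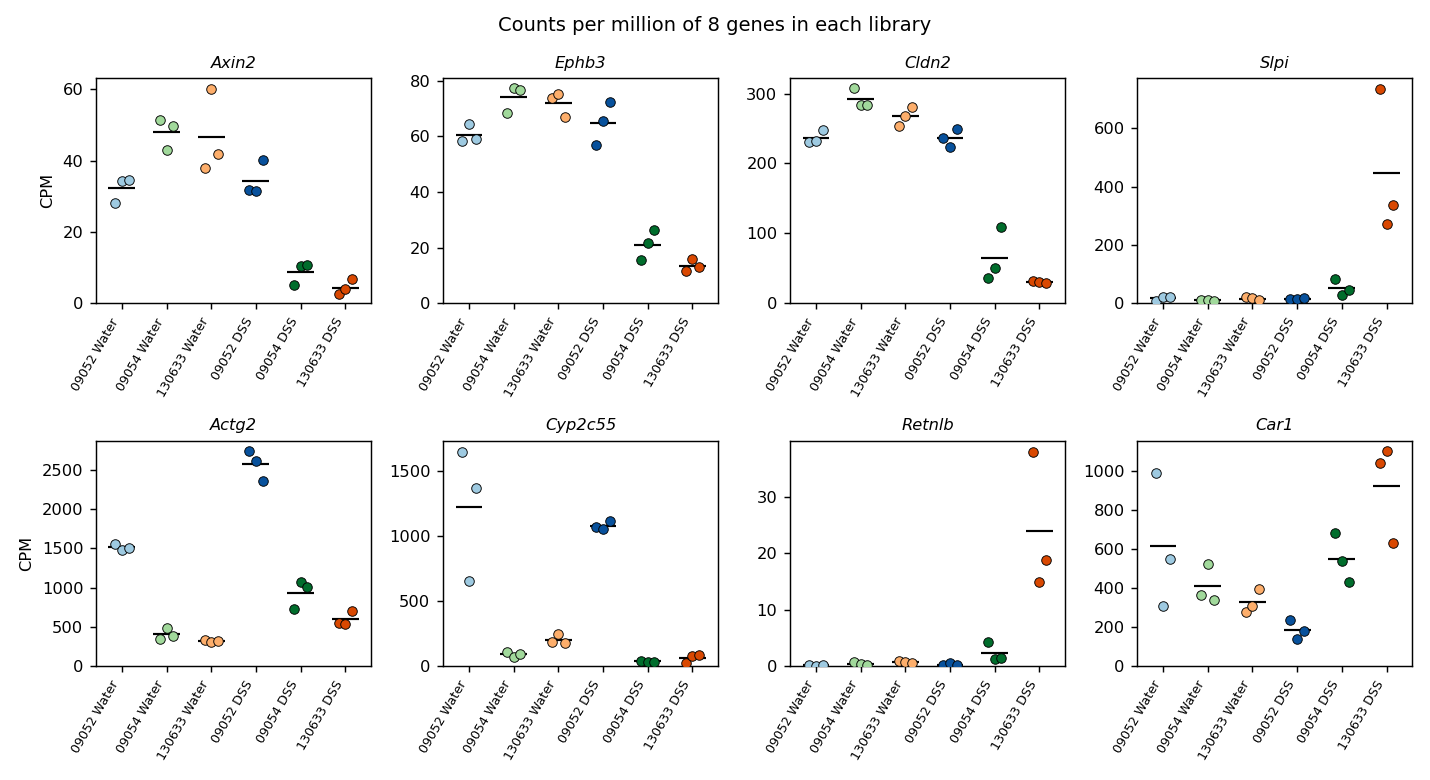
CPM (vertical axes) of Axin2, Ephb3, Cldn2, Slpi, Actg2, Cyp2c55, Retnlb and Car1 in the 6 groups (horizontal axes); points are libraries and lines are group means. Axin2, Ephb3 and Cldn2 lie low with DSS on TD.130633 and TD.09054, and Slpi and Retnlb lie highest with DSS on TD.130633.

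With DSS, TD.130633 had higher levels of mucosal defence and goblet cell genes than the mean of the other diets. Slpi was at 448 ± 251 CPM on TD.130633, 51.9 ± 27.9 on TD.09054 and 15.5 ± 3.43 on TD.09052 (3.98 ± 0.36, adjusted p = 2.99e-05), and Retnlb, a goblet cell protein that binds bacteria (chromosome 16, 48816856 to 48818892), at 23.9 ± 12.4, 2.28 ± 1.69 and 0.228 ± 0.223 CPM (adjusted p = 6.8e-05). Of 20 antimicrobial genes 7 were higher and 1 lower (8 and 1 adjusted over the list alone), with 4 higher without TD.130633 DSS replicate 1. As a set these genes had a camera adjusted p = 0.0349, and an adjusted p = 0.69 with an estimated correlation. Of 14 goblet cell genes 8 were higher (9 adjusted over the list alone), among them Muc2 at 0.57 ± 0.13, Agr2 at 0.84 ± 0.16 and Spink4 at 1.00 ± 0.18; the count was 5 without TD.130633 DSS replicate 2. Tested together with camera, they had an adjusted p = 0.00148, and an adjusted p = 0.69 with an estimated correlation. Of 16 epithelial repair genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone), among them Plaur, the urokinase receptor, at 2.70 ± 0.33 and the growth factor Areg at 2.82 ± 0.59. Their camera test gave an adjusted p = 0.000227, and an adjusted p = 0.69 with an estimated correlation. Of 14 immediate early genes 6 were higher (7 adjusted over the list alone) and 2 were without TD.130633 DSS replicate 1; Fosb, a stimulus-induced transcription factor, was at 23 ± 6.94, 5.03 ± 2.05 and 1.8 ± 0.284 CPM. Camera gave the list an adjusted p = 0.0105, and an adjusted p = 0.69 with an estimated correlation. The immediate early list was written as a sign of handling, which was not tested as a cause. Aqp4 (chromosome 18, 15389496 to 15410982) was at 66.1 ± 20.4, 13 ± 5.35 and 13.8 ± 5.86 CPM (2.30 ± 0.28, adjusted p = 0.000161).

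Crypt base and smooth muscle genes were lower on TD.130633 with DSS. Ephb3 was at 13.5 ± 2.27 CPM on TD.130633, 21.1 ± 5.48 on TD.09054 and 64.9 ± 7.73 on TD.09052 (-1.45 ± 0.15, adjusted p = 5.56e-05). Of 15 crypt base and Wnt target genes 7 were lower (7 adjusted over the list alone), among them Axin2 at -1.97 ± 0.29, and Cldn2 was lower at -2.05 ± 0.24. The list as a whole had a camera adjusted p = 0.000186, and an adjusted p = 0.0902 with an estimated correlation. Against TD.09054 alone these values were -0.64 for Ephb3, -0.99 for Axin2, which did not pass the test there, and -1.12 for Cldn2, and of the smooth muscle genes Actg2 was at -0.66 and Tagln at -0.80. All 14 smooth muscle genes were lower (14 adjusted over the list alone, median -0.83), 9 without TD.130633 DSS replicate 1, with Actg2 at -1.39 ± 0.14 and Tagln, an actin-binding protein (67.8% of its bases lie in exons that overlap another gene), at -1.02 ± 0.12. As a set these genes had a camera adjusted p = 1.04e-11, and an adjusted p = 0.276 with an estimated correlation. Of 25 cholesterol synthesis genes 20 were higher (22 adjusted over the list alone; camera adjusted p = 8.85e-10, and adjusted p = 0.69 with an estimated correlation), but 3 were without TD.130633 DSS replicate 1. Of 11 neutrophil genes 8 were higher (8 adjusted over the list alone; camera adjusted p = 0.00451, and adjusted p = 0.69 with an estimated correlation), and 0 were called in edgeR without TD.130633 DSS replicate 1. Of 25 cell cycle genes 9 were higher (11 adjusted over the list alone; camera adjusted p = 0.000303, and adjusted p = 0.763 with an estimated correlation) and 1 was without that library.

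In all, 3062 genes differed between TD.130633 and the other diets with DSS, 1779 higher and 1283 lower, and in 1736 the 3 TD.130633 libraries lay beyond all 6 others. Each gene given a value kept its call in all 9 leave-outs, as did 64 of 127 named genes called. The count was 1069 without TD.130633 DSS replicate 1, 1169 without the 3 libraries that lay apart, 949 with these 3 groups fitted alone and 1417 with TD.09054 as the only comparator, against which Slpi, Retnlb, Plaur, Fosb, Aqp4, Ephb3 and Cldn2 still passed and Muc2 (0.44), Agr2 (0.64) and Spink4 (0.71) did not.

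The DSS response itself differed between TD.130633 and the mean of the other diets in 524 genes, 310 with a higher and 214 with a lower response. The responses of Slpi (difference 3.70 ± 0.54, adjusted p = 0.00696) and Agr2 (1.38 ± 0.24, adjusted p = 0.0122) were higher on TD.130633. Anxa3, a membrane-binding annexin, had a difference of 1.18 ± 0.19, Acsm3, a medium-chain acyl-CoA synthetase (37.7% of its bases lie in exons that overlap another gene), of 1.16 ± 0.18 and Car9, a carbonic anhydrase, of 1.17 ± 0.19. Lower were the responses of Hkdc1 (-3.71 ± 0.48, adjusted p = 0.00512), Stra6l, a retinol-binding protein receptor (-2.25 ± 0.33, adjusted p = 0.00696), and Kcnq1 (-1.34 ± 0.20). A lower response was also called for 5 of 15 crypt base and Wnt target genes (7 adjusted over the list alone; camera adjusted p = 0.000139, and adjusted p = 0.104 with an estimated correlation), among them Axin2 at -2.22 ± 0.37 and Ephb3 at -1.55 ± 0.19. Of 25 cholesterol synthesis genes 8 had a higher response (23 adjusted over the list alone; median 1.30; camera adjusted p = 8.12e-12, and adjusted p = 0.559 with an estimated correlation), as did 5 of 25 cell cycle genes (15 adjusted over the list alone; camera adjusted p = 1.12e-07, and adjusted p = 0.559 with an estimated correlation), and 0 of either list were called in edgeR without TD.130633 Water replicate 1. Of 3 goblet cell genes with a higher response, of 14 tested (7 adjusted over the list alone; camera adjusted p = 0.000296, and adjusted p = 0.559 with an estimated correlation), Agr2 kept its call in every leave-out; the count was 1 without TD.130633 Water replicate 1 and 6 without the 3 libraries that lay apart.

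Of 66 named genes called for this difference, 15 kept the call in all 18 leave-outs, among them Slpi, Agr2, Anxa3, Acsm3, Car9, Hkdc1, Stra6l, Kcnq1, Axin2 and Ephb3. Without TD.130633 Water replicates 1, 2 and 3 the count was 45, 45 and 168. Without TD.09054 Water replicates 1, 2 and 3 it was 192, 171 and 238, and without TD.09052 Water replicates 1, 2 and 3 it was 340, 1025 and 224. Without TD.130633 DSS replicates 1 and 3 it was 179 and 1753, without TD.09054 DSS replicates 1 and 3 it was 1039 and 238, and without TD.09052 DSS replicates 2 and 3 it was 220 and 248. It was 1661 with DESeq2 and 0 in edgeR with TD.09054 as the only comparator, where 3225 genes had an unadjusted p under 0.05 and the differences were 2.51 for Slpi, -0.94 for Axin2 and -0.59 for Ephb3.

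The DSS response differed between TD.09052 and TD.09054 in 20 genes, 14 higher and 6 lower on TD.09052, of 1891 with an unadjusted p under 0.05. Ephb3 (difference 1.91 ± 0.22, adjusted p = 0.00211) and Lgr5 (adjusted p = 0.00211; levels as given for each diet) kept the call in all 12 leave-outs. Of 15 crypt base and Wnt target genes 6 had a higher response on TD.09052 (10 adjusted over the list alone; median 0.78; camera adjusted p = 1.49e-12, and adjusted p = 0.000834 with an estimated correlation), among them Axin2 (2.55 ± 0.42), Rnf43, a Wnt receptor ligase (1.18 ± 0.22), and Cdca7 (1.63 ± 0.30); the count was 2 without TD.09054 Water replicate 1. Cldn2 (2.16 ± 0.36) and Reg4, a secreted lectin of crypt cells (1.93 ± 0.34), also had a higher response, and Tac1, the substance P precursor (-2.12 ± 0.34), and Gsdmc2 (-0.79 ± 0.12) a lower one. None of 25 cell cycle genes was called in edgeR over all genes, while 16 were adjusted over the list alone (median 1.33; camera adjusted p = 1.13e-11, and adjusted p = 0.675 with an estimated correlation). Without TD.09054 Water replicates 1, 2 and 3 the count was 2, 3 and 3, and without TD.09052 Water replicates 1, 2 and 3 it was 12, 10 and 9. Without TD.09054 DSS replicates 1, 2 and 3 it was 8, 6 and 34, and without TD.09052 DSS replicates 1, 2 and 3 it was 2, 8 and 3. Axin2, Rnf43, Cdca7, Cldn2, Reg4, Tac1 and Gsdmc2 each lost the call in at least 1 of these. The count was 197 with DESeq2 and 68 without the 3 libraries that lay apart.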

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

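The split tests, the test of a smaller DSS intake and the tests without TD.130633 DSS replicate 1 were written before the result they concern was seen, and all other tests of explanations below were chosen only after the result was seen.

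Genes stood out here because their DSS response differed between diets in the interaction test. Between TD.130633 and the mean of the other diets 524 genes did so. Among those with a mean of at least 5 CPM over all libraries and not left out by the naming rule, log2 differences were largest for Clca4b (5.82), Saa3 (5.35), Prg4 (4.20), Mgat4c (4.07), Slpi (3.70), Ddah1 (3.23), Cwh43 (2.47), Cma1 (2.46), Capg (2.40) and Aqp4 (2.39) in the higher direction, and for Hkdc1 (-3.71), Hbb-bs (-2.98), Il22ra2 (-2.80), Angptl7 (-2.63), Adh6a (-2.55), Mettl7a2 (-2.42, all of its exons used overlap another gene), Scnn1g (-2.39), Gbp4 (-2.34), Stra6l (-2.25) and Axin2 (-2.22) in the lower direction. Of these, Slpi, Hkdc1, Stra6l and Axin2 kept the call whichever library was left out, and the others lost it at least once. Between TD.09052 and TD.09054 20 genes did so, among them Nox1 (2.64), Axin2 (2.55), Cldn2 (2.16), Reg4 (1.93), Ephb3 (1.91), Cdca7 (1.63), Lbh (1.31), Cyp4f16 (1.28), Rnf43 (1.18), Sike1 (0.95), Ascl2 (4.77) and Lgr5 (3.75), and in the lower direction Tac1 (-2.12), Mgp (-1.51), Cxcl16 (-1.34), Sult1c2 (-1.06), Il34 (-1.04) and Gsdmc2 (-0.79). Of these, only Ephb3 and Lgr5 kept the call whichever library was left out. Nox1, Cxcl16 and Il34 have 33.2%, 39.9% and 32.6% of their bases in exons that overlap other genes. Signal outside gene bodies, which was not otherwise used, changed with DSS as the mean of the diets in 210 of 1047 clusters of exons.

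Crypt base genes fell with DSS on TD.130633 and TD.09054, with medians of -2.90 and -2.13 over Axin2, Ephb3, Ascl2, Lgr5, Rnf43 and Cdca7, and had a median of 0.09 on TD.09052. These 6 were the list members called lower with DSS on both TD.130633 and TD.09054, so their medians on those diets are low by selection. They are also the 6 list members whose response was called different between TD.09052 and TD.09054. Over all 15 list members the medians were -0.44 on TD.130633, -0.64 on TD.09054 and 0.10 on TD.09052. Fewer epithelial cells in the tissue is argued against as the whole of this fall by a pan-epithelial list of 20 genes. Its medians were 0.24 on TD.130633 and -0.18 on TD.09054, where the crypt genes fell, and -0.26 on TD.09052. In edgeR 6 of the 20 were called higher and 0 lower on TD.130633. On TD.09054 0 were called higher and 4 lower, so a smaller loss of epithelium there is left open. An exchange of TD.09052 water and DSS libraries is argued against only as the reason for the missing fall. Of the TD.09052 water libraries 0 had a crypt base mean at or below the highest of the 6 DSS libraries of the other diets (-0.97). All 6 TD.09052 libraries lay between -0.27 and 0.19, so no exchange among them could hide a fall. Whether any were exchanged cannot be told from this list, which does not separate water from DSS on TD.09052. A smaller intake of DSS on TD.09052 cannot be told apart from a different response, because the 1307 genes that moved the same way on the other diets moved by a median of 0.48 on TD.09052, against 0.96 and 1.16, the 915 higher genes by 0.61 and the 392 lower ones by only -0.17, and intake is not in the files; the genes were chosen by their calls on the other diets, which by itself makes the value on TD.09052 smaller.

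Smooth muscle genes were higher with DSS and on TD.09052. With DSS they moved by 0.10 (SE 0.12) more than neuron and glia genes, which fits more muscle wall in the pieces and may be due to how tissue was cut. On water, TD.09052 differed from TD.09054 by 0.76 (SE 0.16) more in smooth muscle than in neuron and glia genes, which by itself argues against more of the whole wall there. Fibroblast and matrix genes and adipocyte genes had medians of 1.26 and 1.96 in the same comparison. With DSS, smooth muscle genes were still higher by 0.90 (SE 0.24) more than neuron and glia genes, while these medians were 0.16 and -0.82, so a difference in the makeup of the pieces is left open.

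Neutrophil and cholesterol synthesis genes were higher on TD.130633 than on the other diets with DSS. Without TD.130633 DSS replicate 1, 0 of 8 neutrophil genes were called in edgeR and their median went from 4.91 to 2.20, which fits that this library set the call. For cholesterol synthesis 3 of 20 genes were called and the median went from 1.06 to 0.69, so a setting by this library cannot be told apart from a change in the group with 3 mice. Tissue taken nearer to the caecum cannot be told apart either, as genes of the distal hindgut differed by -0.15 (SE 0.11), a value within 2 SE of 0, with Hoxd12 (-0.73) and Hoxd11 (-0.46) called lower among 5 genes, and 4 of 17 small intestine genes were higher and 2 lower.

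Exchange of group labels was tried for each count. For the mean DSS response 1 of 100 splits called as many genes, the real one with 5235 against 3881 in the highest other. A chance division of the libraries can be excluded there at that resolution. It can also be excluded for TD.130633 and the other diets on water (1 of 100, 321 against 213) and with DSS (1 of 100, 3062 against 2633). For the DSS responses of these diets 1 of 100 splits, the real one, called as many, with 524 against 341 in the highest other. For the response of TD.09052 and TD.09054, 4 of 100 splits, the real one included, called as many as the real 20, a share just under 0.05. For both response comparisons the labels were exchanged within water and within DSS. That also removed any difference between the diets themselves, so these splits cannot test the response alone. Chance is left open for the 524 and the 20 genes as differences of responses. For TD.09052 and TD.09054 the highest other split called 273, several times the real count of 20. Whether a structure of the samples lies behind this was not tested. For 3 against 3 libraries 10 splits are too few for a share under 0.05: the real split called most, 1 of 10, for DSS on TD.130633 (3231, highest other 1), on TD.09054 (3559, highest other 0) and on TD.09052 (282, highest other 0), and between TD.09052 and TD.09054 on water (85, highest other 0) and with DSS (278, highest other 1).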

How the results depend on the processing

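Counts that moved by over 1.5 times are given first, and the cause was not tested. For DSS on TD.130633, called genes went from 3231 to 1581 with the groups fitted alone, and to 1868–3353 with single libraries left out. For DSS on TD.09054, 3559 became 1943–3820. For DSS on TD.09052, 282 became 964 with DESeq2, 11 with the groups alone, 2570 without the 3 libraries that lay apart and 0–925 with single libraries left out (edgeR, 2718 genes with an unadjusted p under 0.05). Between TD.09052 and TD.09054, 85 on water became 257, 45, 138 and 20–212 under the same settings, and 278 with DSS became 706, 155, 587 and 103–330. Between TD.130633 and the other diets, 321 on water became 870, 867, 1501 and 43–407, and 74 with TD.09054 as the only comparator, and 3062 with DSS became 949 with the groups alone, 1169 without the 3 libraries, 1417 with TD.09054 only and 1069–4088. For their DSS responses, 524 became 1661 with DESeq2, 908 with the letter block, 45–1753 with single libraries left out and 0 in edgeR with TD.09054 only (3225 genes with an unadjusted p under 0.05). For the responses of TD.09052 and TD.09054, 20 became 197 with DESeq2, 68 without the 3 libraries and 2–34. Libraries with the same letter showed little pairing as a whole. Their deviations correlated with a median of 0.04 over 45 pairs, from -0.21 to 0.47, against a median of -0.02 for different letters. Of 18 libraries, 9 correlated best with a library of another group that had the same letter. In each group but TD.130633 DSS, the library with letter B lay highest on the first principal component. A difference shared by libraries of a letter is therefore not excluded. Of 400 list tests 151 were called with the preset correlation, 6 with an estimated one and 64 by fry. With DSS on TD.130633 against the other diets, Ccl7 became -0.04 without the 3 libraries, Gbp5 0.04 with TD.09052 only and Cyp2c55 0.78 with TD.09054 only; all other named genes kept their direction. The calls of 781 named values, and not their sizes, were compared. The call held for 767 with all reads, 771 with multi-mapping reads, 768 with coverage, 776 with all exons, 776 with median-of-ratios, 748 without the filter, 730 with the letter block, 752 with exons by overlap and 632 without the 3 libraries. It held for 377 of 555 with the groups alone, 182 of 227 with TD.09052 only, 77 of 227 with TD.09054 only and 6142 of 7917 with single libraries left out. The settings by overlap and without 3 libraries were chosen after seeing the data. In simulated data, 7.5% to 86.6% of genes changed by 1.5 times were found, 56.7% to 98.5% at 2 times and 95.5% to 100% at 4 times, so small changes were missed most in the tests of response differences.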

Other observations

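Enteroendocrine genes rose with DSS on TD.130633. Pyy, the peptide YY gene of colonic L cells, changed by 1.19 ± 0.19 (adjusted p = 0.000718), and was higher than on the other diets with DSS (1.08 ± 0.15, adjusted p = 0.000474), in 3 mice per group. Of 13 enteroendocrine genes 6 rose (6 adjusted over the list alone; camera adjusted p = 0.00508, and adjusted p = 0.397 with an estimated correlation), and 3 did so without TD.130633 DSS replicate 1. Guca2a, which encodes guanylin, a peptide that drives fluid secretion, rose by 2.24 ± 0.33 (adjusted p = 0.000452). Of 24 xenobiotic metabolism genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.00127, and adjusted p = 0.397 with an estimated correlation), among them the cytochrome P450 gene Cyp3a13 at -1.38 ± 0.19 and the carboxylesterase gene Ces2c at -1.56 ± 0.25.

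Signal outside gene bodies also differed between diets with DSS. A single exon on chromosome 6, 94812937 to 94818243 (mm10), 2287 bp from Gm7833, was at 14.4 ± 4.56 CPM on water and 11.2 ± 0.979 with DSS on TD.09052, 19.8 ± 1 and 0.457 ± 0.512 on TD.09054, and 9.97 ± 1.61 and 0 on TD.130633 (mean ± SD, 3 mice each). The difference between the DSS responses of TD.09052 and TD.09054 at this exon had an adjusted p = 0.00352 in edgeR. On single diets, 172 of 1047 clusters changed with DSS on TD.130633, 65 higher and 107 lower, 55 on TD.09054, 13 higher and 42 lower, and 0 in edgeR on TD.09052.

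Across genes, which are not independent replicates, libraries of a group correlated with r between 0.957 and 0.992, and the lowest value between groups was 0.931. Of the exon counts summed over genes in a library, the largest gene held 0.82 to 1.62%. No library was identical to another.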
